A study of Mus musculus with 10 samples.

How the data were processed

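RNA from 10 pools of 35 mouse morulae, 5 with control siRNA and 5 with Smchd1 siRNA, was amplified with the Ribo-SPIA method and sequenced as single-end reads, per the labels' protocols. The authors deposited 1 table of FPKM (fragments per kilobase of transcript, scaled by sequencing depth) for 40670 genes by Entrez number. Per the submitters' processing notes, TopHat2 2.1.1, SAMtools and Cuffdiff 2.2.1 were used with the genome build GRCm38.p4; the order of these steps, the library normalization option and the strand setting are not given in the sources used here. Ribo-SPIA amplification and FPKM scaling can both change how abundant transcripts weigh on the rest, and a gene's FPKM also depends on how Cuffdiff shared reads between overlapping genes.

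Genes were matched by Entrez number to RefSeq on GRCm38.p6, with 39419 of the 40670 matched, and 12049 of the 12227 tested. Gene spans come from that annotation, and siRNA target and match positions come from GENCODE vM21 on the same assembly, 1-based. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used with R 4.3.3 and limma 3.58.1.

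The deposited FPKM are not counts, so no count model was run. Relative depth was read from genes with a mean FPKM under 0.1, where after scaling between libraries 76.8% of 27818 values were whole multiples of the gene's smallest value within 0.01, against 2% by chance. No read counts per gene were recovered, since the value of 1 read depends on gene length. Libraries correlated at 0.921 to 0.950 within groups and 0.917 to 0.940 between groups (Pearson r of log values across genes, which are not independent replicates), and no pair of libraries was identical.

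Each gene with a mean FPKM of at least 1 over all 10 pools was tested with limma on log2(FPKM + 1), with an intensity trend and Benjamini-Hochberg adjustment, called at 0.05. Log2 differences are Smchd1 siRNA minus control siRNA on that scale, which understates changes of low genes. Gene lists were tested with camera in limma at a preset correlation of 0.01, for lists with at least 5 tested members. Smchd1 and the X-linked comparison had exact two-sided permutation tests over the pools. The design, the lists and the alternatives were fixed before the data were examined, except where stated.

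Named genes followed a rule: Smchd1; up to 12 largest rises and falls past the threshold, filled to 6 per direction by smallest p; Cdx2, Nanog, Pou5f1, Gata6 and Xist; and up to 4 passing members, or else the member of smallest p, of each list. Predicted genes were counted and passed over.

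Tested on simulated data for this comparison (5 runs of 12222 genes with the real means and spreads, 50 changed genes per fold size), limma recovered 4.86% of genes changed 1.25-fold, 31.3% at 1.5-fold, 67.5% at 2-fold and 93.2% at 4-fold, and 5.40% of its calls were false. Genes of every fold size were changed in the same run, and genes were drawn independently. Many true changes ease the adjusted threshold, so recovery may be lower where fewer genes change. Camera called 5 of 5 simulated lists of 30 genes shifted by 0.2 log2 and 0 of 120 unshifted lists, in data simulated without correlation between genes.

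The alternatives were pseudocounts of 0.1 and 0.5, no low filter, a mean FPKM of at least 5, quantile scaling, upper-quartile scaling and scaling to equal totals, no trend, a robust prior, sample weights, the replicate number as a block, each pool left out in turn, and for lists an estimated correlation, fry and ranks. Leaving out genes listed at 0 in 1 group, and testing protein-coding genes only, were added after the data were seen. Every per-sample column of the table was used.

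For matches to the siRNAs, all GENCODE transcripts of a tested gene were searched for the longest stretch shared with a target, and the longest annotated 3' UTR for 7-base sites of the guide seeds. Genes with no annotated 3' UTR were counted as not searched. For Rps4l, every 50-base stretch of its GENCODE transcripts was looked up in the transcripts of all other genes, with exact matches counted on both strands.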

Results

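The series asked what happens to gene expression in mouse morulae when Smchd1 is knocked down from the zygote onward. Smchd1 is a chromatin protein of the SMC hinge-domain family with known roles in X inactivation and in silencing imprinted and clustered genes. Zygotes of B6D2F1 mice received about 10 pl of 100 µM siRNA in the cytoplasm, either a mixture of 4 siRNAs against Smchd1 or a scrambled control. RNA came from pools of 35 morulae at 93 h after hCG, with 5 pools per group, and the labels call each pool an independent biological replicate. The labels call the group a knockout in places, but the treatment was an siRNA knockdown. Expression was deposited as FPKM for 40670 genes, of which 12227 had a mean FPKM of at least 1 and were tested. Relative sequencing depth, recovered from whole-read steps in low genes, ran from 0.809 to 1 across the 10 libraries. One FPKM over 1 kb of transcript corresponded to about 12.4 reads (interquartile range 11.5 to 12.9, from 421 genes with a single transcript). The locus annotated as the small RNA gene Mir6236 took 26.9% of the summed FPKM in control replicate 1 and 39.2% to 43.3% in the other 9 libraries. Which RNA its reads came from was not examined. FPKM is scaled by transcript length, which raises short genes, so these percentages are not a share of reads or of RNA.

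Smchd1 (chromosome 17, 71344489 to 71475366, GRCm38) fell in every Smchd1 siRNA pool. Its level was 7.16 ± 0.608 FPKM in control pools and 2.00 ± 0.428 FPKM in Smchd1 siRNA pools (mean ± SD, n = 5 each), so that 27.9% remained. The log2 difference was -1.45 with a standard error of 0.11 and an adjusted p of 0.00011. The groups did not overlap: control pools lay between 6.35 and 8.03 FPKM and knockdown pools between 1.48 and 2.56 FPKM. An exact two-sided permutation test over all 252 assignments gave p = 0.00794, the smallest it can give. All 4 siRNAs matched the 7052-base Smchd1 transcript of 48 exons inside the coding sequence, on the minus strand of chromosome 17. Their target positions were 71363049 to 71363066 in exon 40 (GAAAUGAACUAAAAGCGU), 71365156 to 71365174 in exon 39 (GAAGGAGAAGGACGAGUUA), 71391409 to 71391427 in exon 26 (CUGUGAAAGAUGUCCGCUA) and 71370964 to 71370982 in exon 35 (CUAACAAGGUGGGAGCAUA). The first of these is 18 bases long in the labels and the others 19.

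Besides Smchd1, few genes were called between the groups, and most of those called fell. Nt5c3b, a cytosolic nucleotidase, fell from 31.8 ± 9.79 to 8.52 ± 2.18 FPKM (log2 -1.76, SE 0.21, adjusted p = 0.00471). Rps4l, which RefSeq classes as a transcribed pseudogene and whose sequence resembles the ribosomal protein gene Rps4x, fell from 90.1 ± 10.9 to 46.5 ± 4.001 FPKM (log2 -0.93, SE 0.10, adjusted p = 0.00182). Psmc2, an ATPase subunit of the proteasome, fell from 139 ± 6.05 to 83.7 ± 7.13 FPKM (log2 -0.73, SE 0.07, adjusted p = 0.00156). Lcmt2, a tRNA-modifying enzyme, was the 1 called gene estimated in both groups that rose, from 10.3 ± 0.594 to 16.9 ± 1.19 FPKM (log2 0.66, SE 0.07, adjusted p = 0.00269). Skp2, the substrate-binding subunit of a ubiquitin ligase, fell by 0.75 on the log2 scale (adjusted p = 0.0481). Lclat1, an acyltransferase of cardiolipin remodelling, fell by 0.54 (adjusted p = 0.0481), and Srpr, a subunit of the signal recognition particle receptor, fell by 0.45 (adjusted p = 0.0388). In each of these 8 genes, Smchd1 included, all 5 Smchd1 siRNA pools lay beyond every control pool; chance separates 0.794% of unselected genes, but these genes were picked by limma on the same pools, so the separation is no further evidence.

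**Figure D1:**
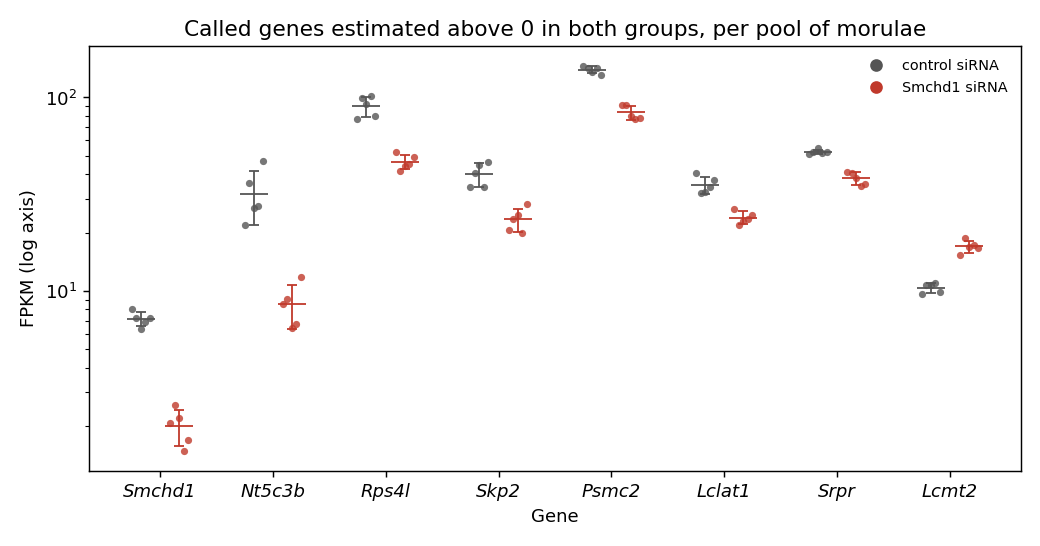
FPKM on a log axis for the 8 genes called between the groups and estimated above 0 in both; each point is 1 pool of 35 morulae, horizontal bars are means and error bars are SDs (n = 5). Smchd1 pools lie between 1.48 and 2.56 FPKM after Smchd1 siRNA and between 6.35 and 8.03 FPKM in controls; Lcmt2 alone is higher after Smchd1 siRNA.

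In all, limma called 13 genes at an adjusted p under 0.05, 3 higher and 10 lower, and 993 genes had an unadjusted p under 0.05 where 611 would be expected by chance. Of the 13, 5 were listed at 0 in every pool of 1 group and are given below by pool. When those 5 genes were left out, an alternative added after the data were seen, 5 genes remained called: Smchd1, Nt5c3b, Rps4l, Psmc2 and Lcmt2. Skp2, Lclat1 and Srpr then had adjusted p of 0.0781, 0.0781 and 0.0710; over their 23 alternatives adjusted p ran from 0.00304 to 0.196 for Skp2, from 0.0139 to 0.338 for Lclat1 and from 0.0181 to 0.292 for Srpr. Leaving out single pools also ended these 3 calls: Skp2 passed only without Smchd1 replicate 5 (adjusted p = 0.0361), Srpr only without Smchd1 replicate 1 (adjusted p = 0.0289) and Lclat1 in none of the 10 fits. Nt5c3b, Rps4l, Psmc2 and Lcmt2 stayed called in all 10; over all alternatives Nt5c3b, Psmc2 and Lcmt2 were called in 23 of 23 and Rps4l in 21 of 22, with an adjusted p of up to 0.0618.

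Several of these transcripts carry sequence shared with an siRNA or with another gene. Psmc2 holds a 13-base match to the second siRNA target (AGGAGAAGGACGA, guide positions 5 to 17, chromosome 5, 21786858 to 21786870, exon 2). Nt5c3b holds a 13-base match to the same siRNA (GGAGAAGGACGAG, guide positions 4 to 16, chromosome 11, 100429890 to 100429902, exon 9). Srpr holds a 13-base match to the fourth siRNA (ACAAGGTGGGAGC, guide positions 4 to 16, chromosome 9, across the junction of exons 13 and 14 between 35215809 and 35215945). All 3 matches lie in coding sequence, and 56 of the 9926 tested genes searched, or 0.564%, held a match of at least 13 bases. Of 894 stretches of 50 bases, the read length, in Rps4l transcripts, 0 occur in transcripts of Rps4x (log2 -0.16, adjusted p = 0.776) and 133 in those of another pseudogene, Rps4l-ps, a count made after the data were seen. Nt5c3b overlaps Klhl10 (log2 -0.11), Lcmt2 overlaps Adal (log2 0.01), Srpr overlaps Fam118b (log2 -0.04) and Skp2 overlaps Lmbrd2 (log2 -0.11). None of these 4 neighbours passed the test. Rps4l also overlaps Tmtc1, Nt5c3b overlaps Fkbp10 and Lclat1 overlaps Gm9311 and Gm25406, none of which was tested. The strand setting of the libraries was not given in the sources used here.

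The 5 genes listed at 0 in 1 group included neighbouring pairs. The mitochondrial genes ND4L and ND4 were listed at 0 in all 5 Smchd1 siRNA pools. In control replicates 1 to 5, ND4L stood at 32366, 19269, 23715, 28976 and 38109 FPKM and ND4 at 11861, 6281, 7713, 8653 and 9628 FPKM. Hexb, a lysosomal hexosaminidase subunit, and Gfm2, a factor of mitochondrial translation, were listed at 0 in all 5 control pools. In Smchd1 siRNA replicates 1 to 5, Hexb stood at 22.4, 25.7, 31.8, 30.1 and 26.6 FPKM and Gfm2 at 7.46, 5.38, 5.21, 5.49 and 4.34 FPKM. Gm38476, a predicted gene named here after its values were seen, was listed at 0 in all Smchd1 siRNA pools and at 1.32, 1.65, 3.09, 1.65 and 3.83 FPKM in control replicates 1 to 5. ATP6, ATP8 and COX3, which every cell uses, were listed at 0 in all 10 pools, so a listed 0 need not be an absent transcript, and no fold is given for these genes.

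Among genes with higher FPKM after Smchd1 siRNA, those with the smallest p that did not pass were Oscp1, Ubap1l and Nme7. Oscp1 stood at 7.56 ± 0.884 FPKM in controls and 11.5 ± 1.17 FPKM after Smchd1 siRNA (log2 0.55, adjusted p = 0.0981). Ubap1l had a log2 difference of 0.38 (adjusted p = 0.186) and Nme7 of 0.37 (adjusted p = 0.232). None of these 3 genes passed in any of the 23 alternative settings.

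Transcripts of the lineage regulators of the morula did not differ detectably between the groups. Cdx2, the trophectoderm regulator, was at 20.4 ± 1.64 FPKM in controls and 21.7 ± 1.58 FPKM after Smchd1 siRNA (log2 0.09, SE 0.08). Nanog was at 325 ± 41.4 and 339 ± 48.4 FPKM (log2 0.06, SE 0.12), and Pou5f1 at 152 ± 23.0 and 143 ± 13.1 FPKM (log2 -0.07, SE 0.11). Gata6, a primitive endoderm regulator, was at 90.8 ± 13.9 and 94.97 ± 6.72 FPKM (log2 0.07, SE 0.10). Adjusted p was 0.786 for Cdx2, 0.921 for Nanog, 0.888 for Pou5f1 and 0.877 for Gata6.

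Gene lists fixed before the data were examined moved by small amounts. Of 25 lists with at least 5 tested members, camera with its preset correlation called 9, 4 higher and 5 lower. List medians and counts of members are given against 0. All tested genes had a median log2 of -0.02, and those with a mean FPKM of at least 5 had -0.04. The DNA replication and cell cycle list lay lower (median log2 -0.11, 30 of 37 members below 0, adjusted p = 0.00535; adjusted p = 0.163 with an estimated correlation). Its member with the smallest p, the replication helicase subunit Mcm6, had a log2 difference of -0.36 (adjusted p = 0.254). The pluripotency and inner cell mass list lay lower (median log2 -0.12, 18 of 24 below 0, adjusted p = 0.0117; adjusted p = 0.163 with an estimated correlation), with Lin28a at log2 -0.33. The DNA methylation and heterochromatin list lay lower (median log2 -0.09, 42 of 54 below 0, adjusted p = 0.0117; adjusted p = 0.163 with an estimated correlation), with the methyltransferase gene Dnmt3a at log2 -0.32. The list of genes active at the 2-cell stage lay lower (median log2 -0.20, 15 of 17 below 0, adjusted p = 0.0191; adjusted p = 0.227 with an estimated correlation), with the phosphatase gene Cdc25c at log2 -0.32.

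Among lists called higher, nuclear oxidative phosphorylation genes had a median log2 of 0.07 (69 of 91 above 0, adjusted p = 0.00535; adjusted p = 0.697 with an estimated correlation). Cholesterol biosynthesis genes had a median log2 of 0.17 (17 of 23 above 0, adjusted p = 0.0191; adjusted p = 0.697 with an estimated correlation), although Dhcr7, the member with the smallest p, had a log2 of -0.20. All 7 tested members of the X-linked multicopy Xlr and Rhox list lay above 0 (median log2 0.21, adjusted p = 0.0191; adjusted p = 0.163 with an estimated correlation), with Rhox9 at log2 0.65. The trophectoderm list had a median log2 of 0.09 (15 of 22 above 0, adjusted p = 0.0456; adjusted p = 0.697 with an estimated correlation), with Tspan8 at log2 0.55. The mitochondrially encoded list was called lower (adjusted p = 0.0456; adjusted p = 0.697 with an estimated correlation) because of ND4 and ND4L alone: its mean log2 was -2.67, but its median was 0.11 and the other 8 members lay above 0.

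No member of these lists other than ND4 and ND4L passed over all genes, and adjusted over the list alone only Mcm6 passed besides those 2. With an estimated correlation 0 of the 25 lists passed, while 5 passed by fry, which tests whether genes of a list move one way and does not compare them with other genes. Without Smchd1 replicate 4, only 2 lists passed, DNA replication (adjusted p = 0.0221) and DNA methylation and heterochromatin (adjusted p = 0.0336).

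Other settings ended some of these list calls or moved their medians by over 1.5 times. With no low filter the Xlr and Rhox list had 20 members, a median log2 of 0.04 and no call (adjusted p = 0.498), and by fry it did not pass either (adjusted p = 0.0836). Under quantile scaling the pluripotency list had a median log2 of -0.06 and did not pass (adjusted p = 0.121); under upper-quartile scaling its median was -0.07 and it passed (adjusted p = 0.0115). The DNA replication list passed under both scalings with medians of -0.05 and -0.06, as did the DNA methylation and heterochromatin list with medians of -0.05 and -0.05. Nuclear oxidative phosphorylation genes had medians of 0.11 and 0.12 under the same scalings. The mitochondrial list lost its call under quantile scaling (median 0.28, adjusted p = 0.829), with sample weights (median 0.18, adjusted p = 0.305), with a mean FPKM of at least 5 (adjusted p = 0.0971) and with no trend (adjusted p = 0.0568). The trophectoderm list lost its call on equal totals (adjusted p = 0.0719), with no trend (adjusted p = 0.0568), with sample weights (adjusted p = 0.0546) and on ranks (adjusted p = 0.0612).

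Single pools also carried much of some medians. The cholesterol median was 0.05 without control replicate 5 (adjusted p = 0.304), 0.09 without Smchd1 replicate 1 (adjusted p = 0.340) and 0.30 without Smchd1 replicate 5 (adjusted p = 0.000109). The oxidative phosphorylation median was 0.04 without control replicate 5, 0.03 without Smchd1 replicate 4 and 0.11 without Smchd1 replicate 5. The trophectoderm median was 0.15 without control replicate 1, 0.05 without control replicate 3, 0.06 without control replicate 5, 0.03 without Smchd1 replicate 1 and 0.05 without Smchd1 replicate 4. The Xlr and Rhox median was 0.34 without control replicate 2, 0.13 without Smchd1 replicate 4 and 0.35 without Smchd1 replicate 5, and the pluripotency median was -0.18 without control replicate 1. The mitochondrial median was 0.22 without control replicate 1, 0.000386 without control replicate 2 and 0.18 without control replicate 5.

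**Figure D2:**
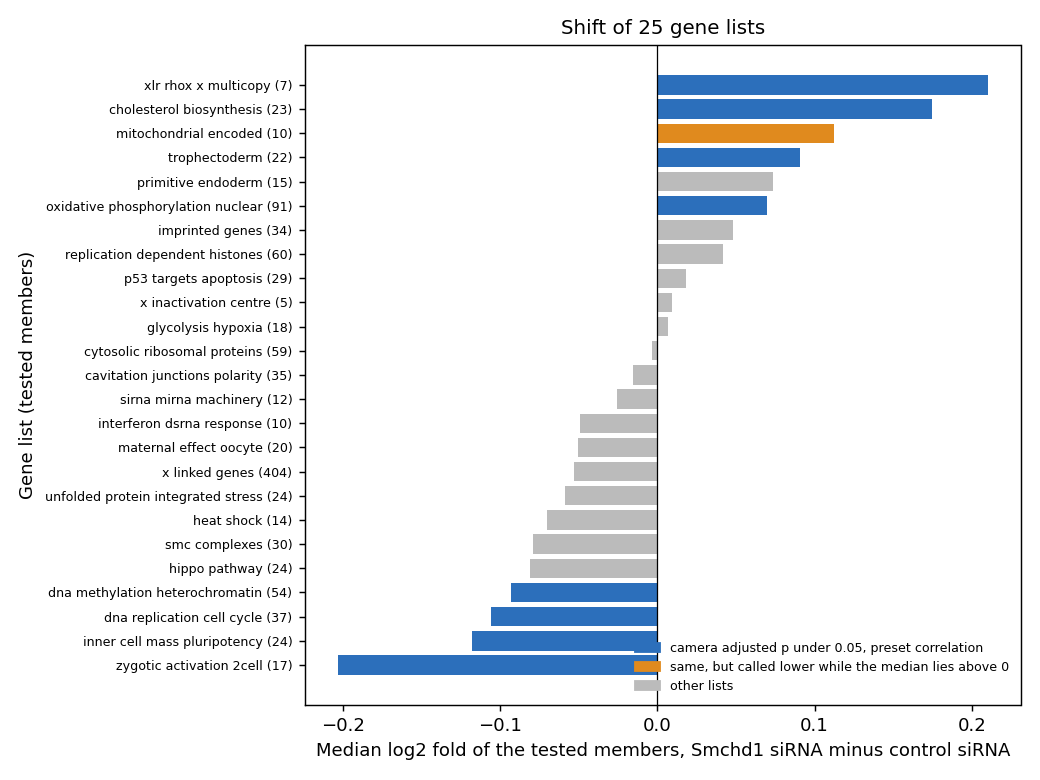
Median log2 difference of the tested members of 25 gene lists, Smchd1 siRNA minus control siRNA, with the number of tested members in brackets. Blue bars passed camera at an adjusted p under 0.05 with the preset correlation, the orange bar was called lower while its median lies above 0, and grey bars did not pass; medians lie between -0.20 and 0.21.

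The other 16 lists did not pass. Lists nearest the threshold were the Hippo pathway (median log2 -0.08, adjusted p = 0.0572, Taok1 at log2 -0.25), SMC complexes (median log2 -0.08, adjusted p = 0.0573, the cohesin gene Rad21 at log2 -0.28), imprinted genes (median log2 0.05, adjusted p = 0.0681, Igf2r at log2 -0.41) and replication-dependent histones (median log2 0.04, adjusted p = 0.0697, Hist2h4 at log2 0.54). Adjusted over the list alone, no member of these 4 lists passed. Stress and RNA-response lists did not pass: the unfolded protein list (adjusted p = 0.189, Cth at log2 -0.35), heat shock (adjusted p = 0.269, Dnaja1 at log2 -0.23), p53 targets (adjusted p = 0.321, Bbc3 at log2 0.28), siRNA machinery (adjusted p = 0.566, Dicer1 at log2 -0.17) and the interferon response (adjusted p = 0.646, Bst2 at log2 0.38). Embryo lists did not pass either: primitive endoderm (adjusted p = 0.465, Gata4 at log2 -0.46), junctions and polarity (adjusted p = 0.920, Cldn4 at log2 0.23) and maternal genes (adjusted p = 0.974, Tcl1 at log2 0.43). Glycolysis genes (adjusted p = 0.974, Hk2 at log2 -0.29) and cytosolic ribosomal proteins (adjusted p = 0.920) had median log2 values of 0.01 and -0.00365, and Ndufb10 of the oxidative phosphorylation list had a log2 of -0.27. Rps4l, a transcribed pseudogene that the list takes in by its symbol, was the 1 ribosomal list member of 59 that passed. The camera direction was higher for ribosomal proteins and maternal genes although their medians and means lay below 0, and median and mean differed in sign for the interferon, X-inactivation centre and glycolysis lists.

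Some of these 16 lists passed in an alternative. With no low filter SMC complexes (adjusted p = 0.00754), the Hippo pathway (adjusted p = 0.0245), heat shock (adjusted p = 0.0409) and the unfolded protein list (adjusted p = 0.0467) were called lower. Replication-dependent histones were called higher with a mean FPKM of at least 5 (adjusted p = 0.0138), quantile scaling (adjusted p = 0.0350), sample weights (adjusted p = 0.0123) and protein-coding genes only (adjusted p = 0.0230). The Hippo list also passed with sample weights (adjusted p = 0.0442) and by fry (adjusted p = 0.0263), and ribosomal proteins under quantile scaling (median log2 0.04, adjusted p = 0.0417). With an estimated correlation none of these 6 lists passed, at adjusted p from 0.163 to 0.985. With 1 pool left out, the Hippo list passed without control replicate 2 (adjusted p = 0.0455) or 4 (0.0453) and without Smchd1 replicate 1 (0.0299) or 5 (0.0334), and in its other fits adjusted p reached 0.173. SMC complexes passed without control replicate 4 (adjusted p = 0.0453) or 5 (0.0326) and without Smchd1 replicate 2 (0.0258), and in their other fits adjusted p reached 0.234. Histones passed without control replicate 1 (adjusted p = 0.0173), 2 (0.0462) or 5 (0.0238) and without Smchd1 replicate 1 (0.00837) or 2 (0.0377), but their median was -0.05 without control replicate 3 (adjusted p = 0.717), turning its direction, and 0.01 without Smchd1 replicate 5 (adjusted p = 0.285). The unfolded protein list passed without Smchd1 replicate 1 (adjusted p = 0.0168), and in its other fits adjusted p reached 0.430.

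Gene families known as Smchd1 targets in other tissues mostly had low or zero FPKM here, although a listed 0 need not be an absent transcript. None of the 58 clustered protocadherin genes reached a mean FPKM of 1, the highest being Pcdhgc3 at 0.151, and 2 of 39 Hox genes did, with Hoxd9 highest at 1.76. With no low filter, 36 Hox genes were called higher as a list (median log2 0.02, adjusted p = 0.0467; adjusted p = 0.400 with an estimated correlation) and 45 protocadherin genes were not called (median log2 0.00685, adjusted p = 0.356). Lists of other cell types had too few tested members for a test at a mean FPKM of 1, and none passed with no low filter: 3 of 21 cumulus cell genes, led by Gja1 at 211 FPKM, a connexin that embryos also express, 1 of 19 sperm genes, led by Odf2 at 12.6 FPKM, and 2 of 18 blood and skin genes, led by Krt10 at 1.39 FPKM.

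No shift of X-linked genes against autosomal genes was detected. Over 404 X-linked and 11627 autosomal genes, the median log2 level on the X relative to autosomes was -0.31 ± 0.05 in controls and -0.31 ± 0.07 after Smchd1 siRNA (difference -0.00363, 95% interval -0.0930 to 0.0858, exact two-sided permutation p = 0.929). The interval and the test treat the pools as unpaired, although these values went together by replicate number. Xist, the RNA that coats the inactive X, was at 125 ± 25.2 FPKM in controls and 127 ± 29.5 FPKM after Smchd1 siRNA (log2 0.01, adjusted p = 0.992). By limma, the median log2 difference per gene was -0.05 over X-linked and -0.02 over autosomal genes. The permutation test used the medians per pool and did not test these 2 values. By limma, 0 X-linked genes passed over all genes. Of the 404, 45 had an unadjusted p under 0.05, against 993 of all 12227 tested genes. The X-linked list did not pass camera (median log2 -0.05, adjusted p = 0.240). Adjusted over the list alone, 2 of its 404 members were lower, Gpkow (log2 -0.55, adjusted p = 0.0981 over all genes, and 0.0495 with protein-coding genes only, its 1 call in 23 alternatives) and Fam50a, the latter named after its values were seen. Nor did the X-inactivation centre list pass (adjusted p = 0.920), with Ftx at log2 0.25.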

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

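Tests on ND4 and ND4L, on overlapping genes listed at 0, on matches of about 13 bases with their cut-offs and shuffles, and on seed sites in Psmc2, Nt5c3b and Srpr alone were chosen after the results were seen; the seed test over all fallen genes and the 15-base, rescaling and regrouping tests were set before those results.

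Within groups of 5 pools, 3 of 94 sets of values held 1 pool far from the other 4, where chance alone gives about 1 in 20 sets, or 4.7 here. Rad21 in control replicate 5 was at 265.7 FPKM, above the 220 to 232 FPKM of the other controls. Control replicate 3 had 23231 genes above 0, fewer than the 23704 to 23771 of the other controls. Mir6236 took 26.9% of summed FPKM in control replicate 1, below the 40.0% to 41.4% of the other controls.

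Regrouping the pools tested whether chance could give as many calls. Of 100 splits of the 10 pools into 2 groups of 5, the real one included, 1 gave as many called genes as the real 13, and the highest other split gave 2. For genes estimated above 0 in both groups, 1 of 100 gave as many as the real 8, with 2 the highest other. The genes listed at 0 stayed in these fits and passed only in the real split, where their very small p lowers the adjusted p of the rest. Without them the real split called 5 genes, and the other splits were not run that way. For gene lists, 2 of 100 gave as many as the real 9, but the highest other split also gave 9 and the median other split gave 4, so single list calls with the preset correlation carry little weight.

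The genes listed at 0 in every pool of 1 group are the first pattern. Loss of mitochondrial transcripts as a whole is argued against: the other 8 mitochondrial protein genes had a median log2 of 0.14 (SD 0.07), far from the change ND4 and ND4L would need. Of the 5 genes, 4 overlapped another of the 5 on the chromosome, while no draw of 5 tested genes in 10000 gave more than 2. A failed abundance estimate for overlapping genes in 1 group may therefore account for ND4, ND4L, Hexb and Gfm2. Gm38476 overlaps none of the others, but it overlaps Fdxacb1 (log2 0.17) and Alg9 (log2 -0.02), both estimated above 0 in both groups. Its zeros stay open, as does a change limited to the transcripts listed at 0.

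The 6 genes other than Smchd1 that fell are the second pattern. Scaling as the whole cause is argued against by how little 3 rescalings moved the difference in the median of the 6 in each pool. It went from log2 -0.74 (SE 0.04) to -0.69 (SE 0.05) under quantile and upper-quartile scaling and to -0.73 (SE 0.08) on equal totals. It stayed at least 8.85 standard errors below 0, but the 6 were picked as low on these same pools. That distance is therefore no further evidence. Of the 6, 3 lost their calls under quantile and upper-quartile scaling, and 4 kept theirs on equal totals. No fallen gene reached the 15-base match set as the mark of cleavage, the longest being 13 bases. The mean longest match of the 6, 11.3 bases, nevertheless exceeded all 10000 draws of length-matched genes (median 8.67). Length here was summed over all annotated transcripts of a gene. None of 1000 shuffles of the siRNAs gave 3 genes with 13 bases. At cut-offs of 12, 13 and 14 bases, 3, 3 and 0 fallen genes had a match. Pairing with a guide may therefore, as a hypothesis, account for Psmc2, Nt5c3b and Srpr, of which 0 carry a seed site in the 3' UTR. Their matches start at guide positions 5, 4 and 4, so none holds the whole 7-base seed. The matches of Psmc2 and Nt5c3b also overlap on the same siRNA. Pairing has no such match in Rps4l, Skp2 and Lclat1, whose longest was 11 bases. Skp2 and Lclat1 did carry a 7-base seed site in the 3' UTR, for the first and the second siRNA. Sites in 2 of the 5 genes searched were no clearer than chance (share of length-matched draws 0.156). Rps4l had no annotated 3' UTR to search. An effect of lower Smchd1 stays open for all 6, untested, since every Smchd1 siRNA pool received the same mixture.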

How the results depend on the processing

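Leaving out genes listed at 0 and testing protein-coding genes only were chosen after the data were seen. Smchd1 kept its direction and its call in all 22 alternatives that tested it (log2 -1.81 to -1.39); under the filter of mean FPKM 5 it was not tested. Protein-coding genes only, which leaves out Rps4l, gave 15 calls, 11 of them estimated in both groups. The count of genes estimated above 0 in both groups was 8 and became 5 with no low filter, with upper-quartile scaling, with no trend and with the genes listed at 0 left out, and 5 to 8 with 1 pool left out (5 without control replicate 1, 3, 4 or 5, or Smchd1 replicate 2, 3 or 4); the cause was not tested for the first 3, and leaving out genes with very small p raises the adjusted p of the rest. The count of all called genes, 13, became 5 with the genes listed at 0 left out. List calls, 9, became 13 with no low filter (8 of the 9, 4 others of the 25 lists and the Hox list, tested only there), 0 with an estimated correlation and 5 by fry, and ran from 2 (without Smchd1 replicate 4) to 10 with 1 pool left out; the cause was not tested. The mitochondrial list turned, with a median log2 of 0.14 (adjusted p = 0.0543) with the genes listed at 0 left out and 0.11 (adjusted p = 0.298) on ranks.

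With 1 pool left out, the DNA replication and the DNA methylation lists passed in 10 of 10 fits, the pluripotency list, which also lost its call under quantile scaling (adjusted p = 0.121), in 9 (lost without Smchd1 replicate 4, adjusted p = 0.0501), 2-cell genes in 8 (control 4, Smchd1 4), Xlr and Rhox in 8 (control 5, Smchd1 4), cholesterol in 7 (control 5, Smchd1 1 and 4), oxidative phosphorylation in 7 (control 1 and 5, Smchd1 4), the mitochondrial list in 5 (control 1 and 5, Smchd1 1, 2 and 4) and trophectoderm in 4 (control 2, 3, 4 and 5, Smchd1 1 and 4). Without those pools adjusted p reached 0.124 for 2-cell genes, 0.0831 for Xlr and Rhox and for oxidative phosphorylation, 0.340 for cholesterol, 0.479 for the mitochondrial list and 0.370 for trophectoderm. The X-linked difference did not pass in any alternative.

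Across genes, same-numbered pools deviated together only weakly (r 0.0505 to 0.120, over 0.1 in 2 of 5 pairs), so the pools were not treated as paired. Still, 9 of 10 pools correlated best with their own number. The X-linked minus autosomal median also went together by number. It was -0.305, -0.348, -0.254, -0.260 and -0.367 in control replicates 1 to 5. In Smchd1 siRNA replicates 1 to 5 it was -0.280, -0.397, -0.253, -0.248 and -0.375. By limma, 1792 genes had an unadjusted p under 0.05 with the replicate block, against 993 without it. These are hints from the data, not the design, and whether a number marks a shared day stays undecided. With the replicate block 12 genes were called, 8 of them estimated in both groups and 6 shared with the 8 above; Rps4l had an adjusted p of 0.0618 and Srpr of 0.0833, with log2 values of -0.93 and -0.45 as without it. List calls were 10 with the block: the Hippo list (adjusted p = 0.0429) and SMC complexes (adjusted p = 0.0415) passed and the mitochondrial list did not (adjusted p = 0.381). Of 705 alternative values of uncalled named genes, 6 changed sign, none past the threshold, and 1 passed (Gpkow, protein-coding genes only). The limit that depth sets on low genes was not tested apart from the size of the change.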

Other observations

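The tests of genes with 12-base and 13-base matches to the guide and passenger strands were chosen after the result was seen; the test of seed sites was set before.

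Transcripts that share sequence with the siRNAs but were not called are the third pattern. Of 243 uncalled genes with a match of at least 12 bases to a guide target, 15 had an unadjusted p under 0.05 with a lower level after Smchd1 siRNA and 0 with a higher level, where all tested genes gave 641 lower and 352 higher. Genes of like length, summed over all annotated transcripts of a gene, were the comparison. Against these, however, the 243 differed by -0.0255 on the log2 scale (SE 0.0158, exact two-sided permutation p = 0.143). The 138 genes matching the passenger strand, which gave 13 lower and 2 higher, differed by -0.00464 (exact p = 0.683). At 13 bases the differences were -0.0150 for 53 guide matches (exact p = 0.429) and 0.0248 for 42 passenger matches (exact p = 0.190). Genes with a 7-base guide seed site in the 3' UTR, 1421 of 9683, differed by -0.0122 from those without (SE 0.00657, exact two-sided permutation p = 0.0873). A wider effect of partial pairing with the guides cannot be told apart from none with 5 pools per group, since both differences lie within about 2 standard errors of 0.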
